A study of Mus musculus with 9 samples.

How the data were processed

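ILC2s from lungs of BALB/c mice were profiled in 9 libraries, 3 each of vehicle, DEF, and DEF with FeCl3. The groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were sorted by flow cytometry, RNA was extracted with a column kit, and cDNA was made with the SMARTer Ultra Low Input v3 kit, which adds no molecular identifiers. Reads that were copies of a molecule are therefore counted more than once, and intervals and floors given here cover counting error only. Whether reads were counted by strand is not given in the sources used here. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

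The deposited values are expected counts, that is, estimated reads per gene that need not be whole. They are not scaled to a common total. Per the submitters' processing notes, STAR 2.7.8 and Partek 10.0 were used with the mm10 genome, and DESeq2 is also named there. Their roles, the quantifier and the annotation are not given in the sources used here. The table holds 18902 genes, none with a total under 10 over the 9 libraries, and 37.5% of its values are not whole (27.9% lie further than 0.01 from a whole number). The expected counts were rounded to whole numbers. All 9 columns matched a sample by its description. Totals ranged from 10102180 to 25295252 counts per library.

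Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total 15), which left 14029. Libraries were scaled by TMM, with mean factors of 1.10 in vehicle, 0.894 in DEF and 1.02 in DEF with FeCl3. All 9 libraries entered a quasi-likelihood fit of 3 groups with 6 residual degrees of freedom and a common biological coefficient of variation of 0.160. This fit gives each gene the same spread in all groups. The median SD was 0.09, 0.12 and 0.21 log2 units in vehicle, DEF and DEF with FeCl3. P-values of the fit may therefore be too large for DEF against vehicle and too small where DEF with FeCl3 is compared. The 3 comparisons were tested 2-sided with edgeR's quasi-likelihood F-test. Each adjusted p of a gene is from this test with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. CPM were taken over the TMM-scaled library size, and log2 CPM used a prior count of 2. A fold against a group without counts was set against a floor of 3 counts over the whole group, and a ratio to a group with 1 to 3 counts carries a 95% Poisson counting interval. A duplicate check found no pair of libraries within sampling noise. DEF replicates 1 and 2, whose submitter codes are nearly alike, had a chi-square per degree of freedom of 7.36, within the 2.94 to 54.8 of all pairs within groups. The check finds copies of 1 library. It cannot tell separate samples from repeat libraries of 1 sample, so DEF may hold 2 samples in place of 3. DEF replicates 1 and 2 were the closest DEF pair. Their Spearman correlation was 0.991, against 0.989 and 0.988 for the other DEF pairs. Their median difference was 0.124 log2 units, against 0.136 and 0.165. These values do not settle the question, and replicates 1 and 2 were merged as an alternative.

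Gene lists for pathways, ILC2 functions and markers of other cells, 37 in all, were fixed before the data were examined. So were the design, the tests and all but the library-totals alternative. The 28 lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. They were tested again with an estimated correlation and with fry. For each list the genes passing were counted over all genes tested and adjusted over the list alone. The genes named in the text were set by rule. For each comparison these were the 10 largest rises and 10 largest falls among called genes with at least 10 CPM in the higher group and no overlap between the libraries of the groups, leaving out predicted or unnamed genes. To these were added up to 4 members of each list with the lowest p in a comparison, the 10 largest changes in DEF among genes that changed back, and Tfrc, Fth1, Ftl1, Slc40a1, Il5, Il13, Gata3, Il1rl1, Cdkn1a, Mki67, Pdk1 and Ldha in every comparison. A gene named by the rule in a comparison is also given in the others. Some genes that the rule names are not reported here. Actb, Phgdh, Shmt2, Furin, H1f2, H1f4 and Ero1l were chosen after their values were seen, as were H2-Ab1, Ctla4, Tnfrsf9 and Myc in the comparisons in which the rule does not name them.

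For genes that changed in DEF and changed back with FeCl3, the overlap was set beside that of independent lists and beside 20 simulations of 3 unchanged groups. The share regained is the log2 difference between DEF with FeCl3 and DEF as a percent of that between vehicle and DEF. The analysis was tested on simulated data for DEF against vehicle over 14029 genes. It called 31.3% of 67 genes changed 1.5-fold, 70.1% of 67 changed 2-fold, 89.4% of 66 changed 4-fold and 0.0579% of 13808 unchanged genes. The simulation left most genes unchanged, whereas 8403 of 14029 were called in the data. These rates depend on the share of changed genes, so they do not carry over to the real comparison. Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper-quartile factors, other filters and only the groups compared. Others were the replicate number as a block, DEF replicates 1 and 2 merged, a minimum log2 fold change of 1, library sizes without mitochondrially encoded genes, leaving out each library, and, chosen after the data were seen, library totals without TMM factors. Gene positions are those of GENCODE vM21 on mm10, counted from 1, which holds 18446 of the 18902 symbols (97.6%). Of 266 genes covered by the naming rule or chosen after, 52 have exons that overlap another gene of the table, and reads of such pairs cannot be told apart here.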

Results

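RNA-seq was used to measure transcript levels in group 2 innate lymphoid cells (ILC2s), lymphocytes that secrete type 2 cytokines, sorted from the lungs of BALB/c mice. The mice had received 0.5 µg of recombinant mouse IL-33, an alarmin that activates ILC2s, through the nose on each of 3 days. The cells were taken on day 4. The sorted cells were kept for 18 h with water as vehicle or with 500 µM of an iron chelator that the labels call DEF. In the 8 h that followed, the chelated cells did or did not receive 200 µM FeCl3. This gave 3 groups of 3 libraries each, called vehicle, DEF, and DEF with FeCl3. DEF replicates 1 and 2 carry nearly the same submitter code, and whether they are separate samples or repeat libraries of 1 sample is not given in the sources used here. The vehicle libraries held 14463606, 10102180 and 14391328 counts for replicates 1, 2 and 3. The DEF libraries held 12460581, 25295252 and 10753105 counts, and the DEF with FeCl3 libraries 22814447, 13704865 and 12668327. Of 18902 genes in the table, 14029 passed the filter on low counts and were tested. Levels are in CPM, the counts of a gene relative to the TMM-scaled total of its library, given as mean ± SD over the 3 libraries of a group. Log2 fold changes carry their standard error.

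The libraries separated by group. The first principal component, which held 61.8% of the variance, set the DEF libraries apart from vehicle. The DEF with FeCl3 libraries lay between them. The second component, with 17.5%, set the DEF with FeCl3 libraries apart from the others. The third, with 6.53%, separated DEF with FeCl3 replicates 1 and 3. Spearman correlations between libraries across genes were 0.993 to 0.994 within vehicle, 0.988 to 0.991 within DEF and 0.971 to 0.984 within DEF with FeCl3. They were 0.883 to 0.887 between vehicle and DEF, 0.908 to 0.927 between DEF and DEF with FeCl3, and 0.950 to 0.957 between vehicle and DEF with FeCl3. The DEF with FeCl3 libraries were the most spread of the 3 groups, with a median SD across genes of 0.21 log2 units against 0.09 in vehicle and 0.12 in DEF. The 10 most abundant genes took 7.15% ± 0.0373 of the counts in vehicle, 11.4% ± 0.129 in DEF and 9.52% ± 0.764 with FeCl3. Mitochondrially encoded genes took 0.499% ± 0.0737, 0.613% ± 0.0690 and 0.257% ± 0.0398 (SD, n = 3).

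**Figure D1:**
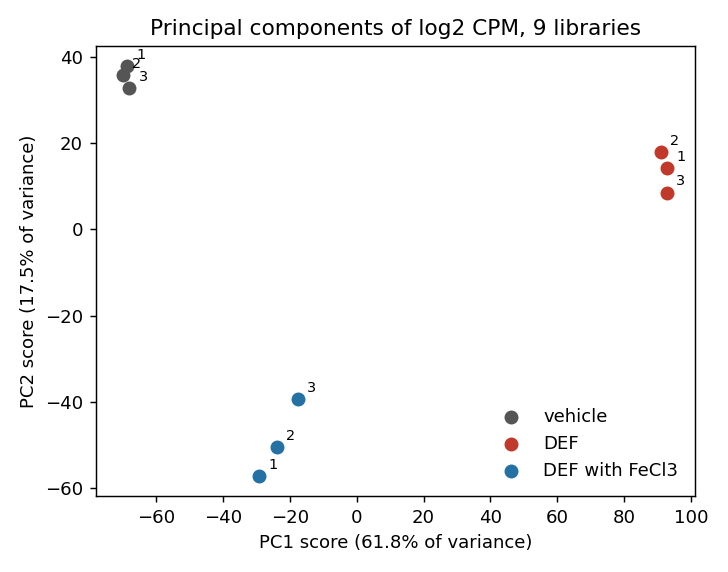
Scores of the 9 libraries on the first 2 principal components of log2 CPM over the 14029 tested genes, in units of the component scores, with each point a library numbered by its replicate and coloured by group. The first component (61.8% of the variance) separates vehicle from DEF, with the DEF with FeCl3 libraries between them.

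The comparison of DEF with vehicle asks which transcripts differ after chelation of iron. Ndrg1, a stress gene induced in hypoxia and by loss of iron, rose from 25.3 ± 2.00 to 2112 ± 97.5 CPM (log2 fold change 6.39 ± 0.11, adjusted p = 5.22e-13, n = 3 per group in an edgeR fit of all genes). Vegfa, the angiogenic growth factor, rose from 13.7 ± 0.941 to 526 ± 13.6 CPM. The glucose transporter gene Slc2a3 rose from 85.4 ± 8.79 to 1746 ± 135 CPM. Il5, the cytokine that drives eosinophil production, rose from 7340.0 ± 236 to 33212 ± 1980.1 CPM (log2 fold change 2.18 ± 0.09, adjusted p = 7.26e-10). Mcm2, a subunit of the replicative helicase, fell from 406 ± 9.79 to 46.0 ± 0.645 CPM. Srm, which encodes spermidine synthase, fell from 118 ± 5.67 to 14.4 ± 0.897 CPM. In all, 8403 of the 14029 genes changed at an adjusted p under 0.05 (4227 higher and 4176 lower). Of these, 2434 were at least 2-fold higher and 2344 at least 2-fold lower. Scaled by library totals alone, an alternative chosen after the values were seen, 35.4% of 8615 changed genes were higher, against 50.3% under TMM. The median log2 fold change of all genes then moved to -0.30. The log2 changes given here are under TMM.

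Of the 39 tested target genes of hypoxia-inducible factor (HIF), the transcription factor stabilised when oxygen or iron is short, 38 rose, 0 fell and 1 did not pass the test (median log2 fold change 2.99, camera adjusted p = 4.26e-19). The call held with an estimated correlation between genes (adjusted p = 0.00264). Mxi1, a repressor of MYC activity, rose from 23.4 ± 0.948 to 433 ± 16.1 CPM. P4ha2, a collagen prolyl hydroxylase, rose from 58.8 ± 6.78 to 1388 ± 123 CPM. All 21 tested glycolytic genes rose (median 1.81, camera adjusted p = 1.38e-11, and adjusted p = 0.0922 with an estimated correlation). Among them were the neuronal enolase gene Eno2, from 7.19 ± 0.583 to 442 ± 22.5 CPM, the aldolase gene Aldoc, from 9.55 ± 0.277 to 212 ± 5.07 CPM. Ldha, which encodes a lactate dehydrogenase subunit, rose from 4298 ± 154 to 9747 ± 523 CPM. Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, rose from 33.4 ± 4.85 to 185 ± 13.2 CPM (log2 fold change 2.47 ± 0.15, adjusted p = 1.88e-08). Of 23 autophagy and mitophagy genes, 17 rose and 1 fell (median 0.88, camera adjusted p = 4.31e-05, and adjusted p = 0.0901 with an estimated correlation). The mitophagy receptors Bnip3l and Bnip3 rose (log2 fold change 3.45 ± 0.10 and 3.89 ± 0.15). Of 43 genes for dioxygenases that use 2-oxoglutarate and iron(II), 25 rose and 5 fell (median 0.76, camera adjusted p = 0.000199, and adjusted p = 0.154 with an estimated correlation). The HIF list also holds 9 of these genes, all of which rose, such as Egln3 and P4ha1. Of the other 34 genes, 16 rose and 5 fell.

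Of 22 genes of the tricarboxylic acid (TCA) cycle, 18 fell and 1 rose (median -0.67, camera adjusted p = 7.34e-05, and adjusted p = 0.115 with an estimated correlation). The citrate synthase gene Cs fell from 418 ± 15.2 to 157 ± 9.33 CPM. Idh3a, a subunit of isocitrate dehydrogenase, fell from 201.6 ± 8.39 to 50.9 ± 0.848 CPM. Of 61 nuclear genes of respiratory complexes I to IV, 33 fell and 4 rose (median -0.44, camera adjusted p = 0.000963, and adjusted p = 0.649 with an estimated correlation). Ndufa10 and Ndufa12 fell (log2 fold change -1.41 ± 0.12 and -1.91 ± 0.17) and Ndufv3 rose (1.47 ± 0.14). Of 15 nuclear genes of ATP synthase, 13 fell and 0 rose (median -0.66, camera adjusted p = 0.00229, and adjusted p = 0.514 with an estimated correlation). The 15 mitochondrially encoded genes moved apart, and 3 rose, 4 fell and 8 did not pass. Their median was -0.22 and their mean 0.01 (camera adjusted p = 0.901). The cytochrome oxidase gene mt-Co1 rose from 432 ± 24.9 to 1879 ± 312 CPM and the ribosomal RNA gene mt-Rnr1 from 152 ± 44.5 to 438 ± 33.7 CPM. In contrast, mt-Nd3 fell from 16.6 ± 3.86 to 6.50 ± 2.02 CPM.

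Of 31 genes for iron-sulfur cluster and heme synthesis, 17 fell and 7 rose (median -0.63, camera adjusted p = 0.0294, and adjusted p = 0.396 with an estimated correlation). This call was lost among genes of at least 10 CPM (adjusted p = 0.104). The heme synthesis gene Cpox fell (log2 fold change -2.07 ± 0.11), and the iron-sulfur assembly gene Iba57 rose (2.15 ± 0.14). Of 24 iron handling genes, 3 rose, 9 fell and 12 did not pass (median log2 fold change -0.17, camera adjusted p = 0.329). Fbxl5, whose product senses iron and targets IRP2 for degradation, rose from 75.2 ± 2.08 to 258 ± 1.95 CPM. The heme oxygenase gene Hmox1 rose from 43.7 ± 8.40 to 215 ± 9.57 CPM, and Slc11a2, an iron importer, fell from 37.8 ± 3.24 to 18.9 ± 1.28 CPM. Tfrc, the transferrin receptor (chromosome 16, 32608920 to 32632794, plus strand of mm10, protein-coding), stood at 427 ± 16.3 CPM in vehicle and 582 ± 50.7 CPM in DEF (log2 fold change 0.45 ± 0.21, adjusted p = 0.0827). It passed when DEF with FeCl3 replicate 1 (adjusted p = 0.000399) or replicate 3 (0.0239) was left out of the fit, when DEF and vehicle alone were fitted (4.05e-05), and with limma-voom (0.000368). The ferritin genes Fth1 and Ftl1, which encode the iron storage subunits, had log2 fold changes of -0.02 ± 0.10 (adjusted p = 0.895) and -0.04 ± 0.15 (0.817). With library totals alone, Fth1 was lower in DEF (log2 fold change -0.31, adjusted p = 0.0134). Slc40a1, the iron exporter, was under 1 CPM in every group.

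Cell cycle and growth genes were lower in DEF. Of 50 DNA replication genes, 48 fell and 0 rose (median -2.34, camera adjusted p = 7.02e-18, and adjusted p = 0.0922 with an estimated correlation). Mcm6 and the DNA ligase gene Lig1 were among them (log2 fold change -2.71 ± 0.10 and -2.68 ± 0.11). Of 48 G2/M and mitotic genes, 46 fell and 0 rose (median log2 fold change -1.86, camera adjusted p = 8.21e-17), and the call held with an estimated correlation (adjusted p = 0.0233). Mki67, the proliferation marker, fell from 547 ± 13.2 to 91.3 ± 8.77 CPM (log2 fold change -2.58 ± 0.14, adjusted p = 5.85e-09). The topoisomerase gene Top2a fell from 653 ± 26.2 to 104 ± 11.7 CPM. Of 33 ribosome biogenesis genes, 29 fell and 1 rose (median log2 fold change -2.09, camera adjusted p = 1.20e-11), which also held (adjusted p = 0.00264). Nop56 and Nolc1 fell (log2 fold change -2.54 ± 0.11 and -3.15 ± 0.13). Myc, a transcription factor for growth genes, fell from 135 ± 5.92 to 32.1 ± 3.23 CPM. The cytoskeletal gene Actb, chosen after its values were seen, fell from 20114 ± 330.4 to 5851 ± 188 CPM. Of 35 p53 target genes, 13 rose and 10 fell (median log2 fold change 0.13, camera adjusted p = 0.449). The cell cycle inhibitor gene Cdkn1a rose from 306 ± 13.3 to 1079 ± 95.3 CPM and Mdm2, a negative regulator of p53, from 157 ± 4.83 to 555 ± 11.1 CPM. Of 15 BCL2 family genes, 7 rose and 2 fell (camera adjusted p = 0.324). The pro-apoptotic gene Bcl2l11 rose from 5.34 ± 0.948 to 58.5 ± 2.32 CPM and Bid fell from 10.0 ± 0.306 to 1.55 ± 0.465 CPM.

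Of 23 ILC2 effector genes, 11 rose, 5 fell (11 rose and 6 fell when adjusted over the list alone) and 7 did not pass (median log2 fold change 0.35, camera adjusted p = 0.191). Beside Il5, the cytokine genes Il13 and Csf2 rose, from 191 ± 23.9 to 439.7 ± 38.6 CPM (log2 fold change 1.20 ± 0.14, adjusted p = 7.53e-06) and from 214 ± 26.5 to 866 ± 20.4 CPM. Calca, which encodes the neuropeptide CGRP, rose from 11.9 ± 1.000 to 86.6 ± 2.77 CPM. Il5 lies at chromosome 11, 53720794 to 53725106, plus strand, and Il13 at chromosome 11, 53631324 to 53634702, minus strand (mm10, both protein-coding). Il5 took 0.806% of all counts in vehicle, 2.97% in DEF and 2.14% with FeCl3. Exons of Il5 overlap the predicted gene Gm12214, which stood at 17.1 CPM in vehicle and 123 CPM in DEF, so reads of these cannot be separated. Of 47 ILC2 identity and receptor genes, 19 rose and 14 fell (21 rose and 15 fell when adjusted over the list alone; camera adjusted p = 0.324). The costimulatory receptor gene Tnfrsf9 rose from 48.6 ± 8.16 to 3366 ± 128 CPM. The inhibitory receptor gene Ctla4, chosen after its values were seen, rose from 0.809 ± 0.124 CPM (log2 fold change 6.92 ± 0.36). The activation marker gene Cd69 rose from 50.3 ± 1.44 to 227 ± 20.1 CPM. Gata3, the lineage-defining transcription factor, fell from 1288 ± 48.2 to 1049.8 ± 72.5 CPM (log2 fold change -0.30 ± 0.08, adjusted p = 0.00624, and -0.59 with library totals alone). Il1rl1, which encodes the IL-33 receptor, stood at 709 ± 23.9 and 593 ± 102 CPM (log2 fold change -0.26 ± 0.14, adjusted p = 0.135), and was lower with library totals alone (log2 fold change -0.55, adjusted p = 0.00525). It also passed when DEF and vehicle alone were fitted (adjusted p = 0.0308) and with limma-voom (0.0127).

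Of 24 immediate early genes, 19 rose and 2 fell (median 1.46, camera adjusted p = 5.99e-06, and adjusted p = 0.0922 with an estimated correlation). Jun rose from 20.8 ± 2.18 to 499 ± 85.9 CPM and Atf3, a stress-induced transcription factor, from 2.43 ± 1.34 to 221 ± 19.8 CPM. Of 23 NF-kB and inflammatory feedback genes, 18 rose and 3 fell (19 rose and 3 fell when adjusted over the list alone; median 0.90, camera adjusted p = 0.000121, and adjusted p = 0.154 with an estimated correlation). Those that rose include the NF-kB inhibitor Tnfaip3 (log2 fold change 3.50 ± 0.12) and the MAP kinase phosphatase Dusp1 (3.09 ± 0.13). Of 29 heat shock and unfolded protein response genes, 21 rose and 7 fell (median 0.64, camera adjusted p = 0.0242, and adjusted p = 0.111 with an estimated correlation), a call lost among genes of at least 10 CPM (adjusted p = 0.0537). The endoplasmic reticulum chaperone gene Hspa5 rose from 1276 ± 30.5 to 4689.9 ± 66.4 CPM and the mitochondrial chaperone gene Hspd1 fell from 297 ± 6.61 to 60.6 ± 1.44 CPM. Of 43 genes of the ATF4 and amino acid response, 10 rose and 25 fell (12 rose and 25 fell when adjusted over the list alone; median -0.69, camera adjusted p = 0.0365, and adjusted p = 0.345 with an estimated correlation). This call was lost without vehicle replicate 3 (adjusted p = 0.0569) or DEF replicate 2 (0.0507), among genes of at least 10 CPM (0.0538), and with library totals alone (0.0667). The members that rose include Ppp1r15a, a regulator of eIF2α dephosphorylation (log2 fold change 3.24 ± 0.11), and the lipoprotein receptor Vldlr, from 2.10 ± 1.18 to 306 ± 9.64 CPM. The HIF list also holds 3 genes of the ATF4 list, all of which rose. The serine and glycine synthesis genes Phgdh and Shmt2, chosen after their values were seen, fell (log2 fold change -2.80 ± 0.16 and -2.85 ± 0.14).

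Of 23 cholesterol synthesis genes, 15 fell and 1 rose (median -0.80, camera adjusted p = 0.000776, and adjusted p = 0.0922 with an estimated correlation). The sterol reductase gene Dhcr7 fell from 53.8 ± 0.425 to 11.2 ± 0.0548 CPM. The fatty acid, NRF2, glutathione and interferon lists did not pass. Of 37 genes of fatty acid uptake and oxidation, 11 rose and 16 fell (12 rose and 16 fell when adjusted over the list alone; camera adjusted p = 0.62). The fatty acid transporter Slc27a4 rose (log2 fold change 2.52 ± 0.13) and Etfb, of the electron transfer flavoprotein, fell (-2.37 ± 0.19). Of 26 NRF2 target genes, 8 rose and 13 fell (camera adjusted p = 0.43), and the quinone reductase gene Nqo1 fell from 120.4 ± 6.76 to 10.9 ± 0.520 CPM. Of 19 glutathione and ferroptosis genes, 6 rose and 8 fell, and the median of -0.02 and the mean of 0.06 differed in sign (camera adjusted p = 0.603). Of 25 type I interferon genes, 4 rose and 10 fell (camera adjusted p = 0.369). Isg20, an exonuclease gene, rose (log2 fold change 3.48 ± 0.16) and the RNA sensor gene Ddx58 fell (-0.90 ± 0.12).

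The largest rises in DEF, among genes with at least 10 CPM in the higher group, included Ghrh, which encodes growth hormone-releasing hormone (chromosome 2, 157329497 to 157347506, minus strand of mm10). It had no count in vehicle and 47.7 ± 2.36 CPM in DEF, at least 688-fold higher. The T-type calcium channel gene Cacna1h (at least 275-fold), Cstdc4 (at least 277-fold), the mucin gene Muc2 (at least 260.3-fold) and Gad1, which makes GABA (at least 148-fold), likewise had no count in vehicle. With 1 to 3 counts in vehicle, the ratios of CPM were 2162 for the incretin receptor Gipr (counting interval 739 to 10485), 2111 for the transcription factor Ascl2 (378 to 83419.8) and 854 for Coch (292 to 4143). Adm, which encodes the vasodilator peptide adrenomedullin, rose from 0.163 ± 0.184 to 466 ± 20.1 CPM, and Vwa1 from 0.187 ± 0.0644 to 234 ± 40.6 CPM. Some of these values moved by over 1.5-fold when a vehicle library was left out. The fitted log2 fold change of Adm was 11.61, and 10.97 without vehicle replicate 1 or 12.68 without replicate 2. That of Coch was 9.52, and 8.91 or 10.52 without the same libraries. Gipr moved from 10.90 to 10.28 without replicate 1 or 11.69 without replicate 3, and Ascl2 from 10.64 to 12.57 without replicate 1. The largest fall was that of Disp2, from 29.9 ± 2.92 CPM to no count in DEF, at least 429-fold lower. The aldehyde dehydrogenase gene Aldh3a1, the monoamine oxidase gene Maob, the transcription factor gene Msc, the antiviral gene Ifitm3, the T cell receptor gamma constant gene Trgc1 and the histone H2A genes Hist1h2ap, Hist1h2ao, H2ac12 and H2ac8 fell by 4.64 to 5.78 on the log2 scale. Aldh3a1 stood at -8.30 without DEF replicate 1 and -4.83 without DEF replicate 2, and Maob at -5.83 without DEF replicate 2. Trgc1 fell from 113 ± 7.11 to 3.22 ± 0.892 CPM and Hist1h2ap from 692 ± 20.9 to 18.9 ± 2.40 CPM. Histone genes are near-identical copies, so the split of reads between them is uncertain.

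Markers of other cell types were measured beside these groups. Of 12 tested markers of macrophages, monocytes and dendritic cells, 6 rose and 1 fell (median log2 fold change 1.14, camera adjusted p = 0.141). H2-Ab1, a class II antigen presentation gene (chromosome 17, 34257689 to 34269419, plus strand of mm10) chosen after its values were seen, rose from 16.4 ± 1.32 to 372 ± 32.8 CPM. The class II chaperone gene Cd74 rose to 18.7 ± 0.687 CPM (log2 fold change 1.63 ± 0.26). The epithelial marker Epcam rose from 9.94 ± 1.16 CPM (log2 fold change 1.59 ± 0.13), the eosinophil receptor gene Ccr3 from 3.47 ± 0.333 to 11.6 ± 0.519 CPM, and the cytotoxic granule gene Prf1 from 2.08 ± 0.472 to 16.1 ± 2.59 CPM. The hemoglobin gene Hba-a1 fell from 8.18 ± 0.907 to 3.07 ± 1.44 CPM, the B cell gene Cd79b from 13.6 ± 1.02 to 5.97 ± 0.385 CPM, and the T cell receptor gene Trbc2 from 74.7 ± 7.21 to 27.7 ± 0.752 CPM. Of 6 T cell markers, 0 rose and 2 fell (0 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.272). There were 9 further marker lists with fewer than 5 tested genes. In these, 2 of 2 genes rose in the eosinophil, basophil and mast cell list, 2 of 2 in the fibroblast and smooth muscle list, 2 of 4 in the ILC3 list, 1 of 3 in the epithelial list and 1 of 3 in the NK cell and ILC1 list. In the B and plasma cell list 2 of 2 fell, as did 2 of 2 in the red cell list and 1 of 2 in the endothelial list, and the 1 tested neutrophil gene did not pass. Camera called 16 of 28 lists in this comparison, and 3 of these calls held with an estimated correlation. They were those of HIF targets, mitotic genes and ribosome biogenesis. Adjusted over the list alone, the counts were the same as over all genes in 31 of the 37 lists and differed by at most 3 genes in the other 6.

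**Figure D2:**
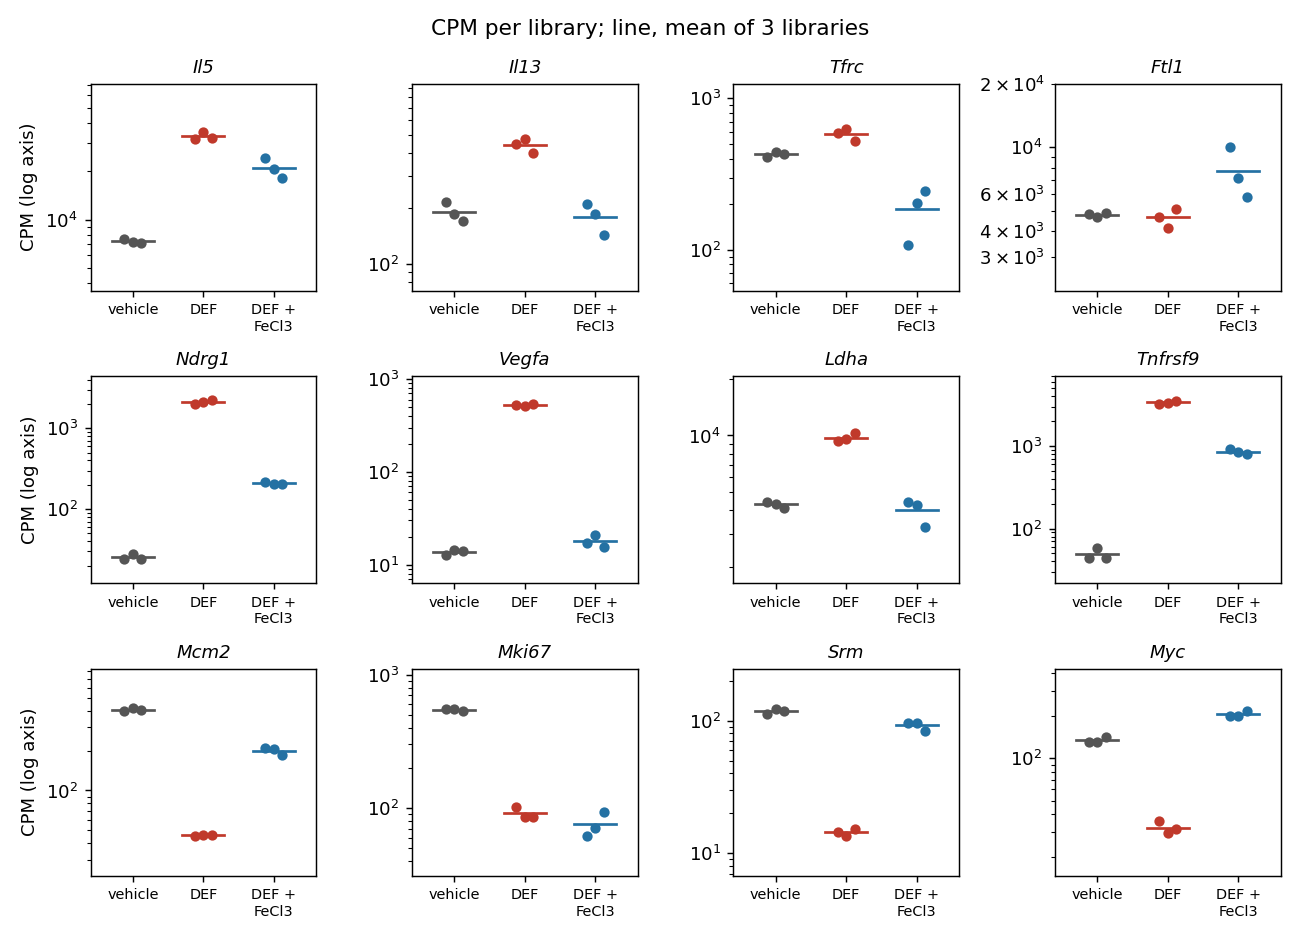
CPM after TMM scaling (log axis) of 12 genes in each of the 9 libraries, with the 3 groups side by side, a point per library and a line at the mean of 3. Il5 stands at 7340.0, 33212 and 20993 CPM in vehicle, DEF and DEF with FeCl3, Vegfa at 13.7, 526 and 17.8, and Mki67 at 547, 91.3 and 75.7.

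The comparison of DEF with FeCl3 against DEF asks what adding iron back changed. Vegfa fell from 526 ± 13.6 to 17.8 ± 2.61 CPM (log2 fold change -4.89 ± 0.13, adjusted p = 6.98e-11). Ndrg1 fell from 2112 ± 97.5 to 208 ± 9.54 CPM. Il13 fell from 439.7 ± 38.6 to 180.4 ± 34.7 CPM (log2 fold change -1.28 ± 0.14, adjusted p = 6.67e-06). Il5 fell from 33212 ± 1980.1 to 20993 ± 3015 CPM (-0.66 ± 0.09, adjusted p = 3.73e-05). Myc rose from 32.1 ± 3.23 to 205 ± 9.80 CPM and Mcm2 from 46.0 ± 0.645 to 200.4 ± 13.1 CPM (log2 fold change 2.12 ± 0.09, adjusted p = 2.29e-09). Of the 14029 genes, 7329 changed (3825 higher and 3504 lower), 1696 at least 2-fold higher and 1835 at least 2-fold lower. With library totals alone, 64.2% of 7571 changed genes were higher, against 52.2% under TMM, and the median log2 fold change of all genes moved to 0.20.

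Iron handling genes moved both ways. Of 24, 11 rose, 4 fell and 9 did not pass (median log2 fold change 0.40, camera adjusted p = 0.215). Tfrc fell from 582 ± 50.7 to 185 ± 70.0 CPM (log2 fold change -1.66 ± 0.22, adjusted p = 2.83e-05), and Fbxl5 and Hmox1 fell (-1.24 ± 0.10 and -1.13 ± 0.13). Ftl1 rose from 4635 ± 483 to 7688 ± 2172 CPM (log2 fold change 0.73 ± 0.15, adjusted p = 0.00118). Fth1 rose from 2324 ± 52.8 to 2949.9 ± 463 CPM (0.34 ± 0.10, adjusted p = 0.0114, and 0.53 with library totals alone). Ftl1 has near-identical pseudogenes, so its count is uncertain. Ftl1 lies at chromosome 7, 45457944 to 45459884, minus strand, and Fth1 at chromosome 19, 9980598 to 9985098, plus strand (mm10, protein-coding). Slc11a2 rose from 18.9 ± 1.28 to 46.0 ± 2.62 CPM. Slc40a1 rose from 0.223 ± 0.119 to 0.885 ± 0.102 CPM (log2 fold change 2.11 ± 0.71, adjusted p = 0.0231). This call was lost without DEF replicate 1 (adjusted p = 0.0555), DEF replicate 2 (0.136), DEF with FeCl3 replicate 1 (0.0508) or DEF with FeCl3 replicate 2 (0.057). It was also lost with no filter on low counts (0.0523) and with DEF replicates 1 and 2 merged (0.0651). Of 31 iron-sulfur and heme synthesis genes, 17 rose and 6 fell (19 rose and 6 fell when adjusted over the list alone; median 0.54, camera adjusted p = 0.0183, and adjusted p = 0.333 with an estimated correlation). This call was lost among genes of at least 10 CPM (adjusted p = 0.0954). The ferredoxin reductase gene Fdxr rose from 2.87 ± 0.486 to 14.5 ± 2.22 CPM.

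Of 39 HIF target genes, 36 fell and 0 rose (median log2 fold change -2.61, camera adjusted p = 2.23e-20), a call that held with an estimated correlation (adjusted p = 0.00304). All 21 glycolytic genes fell (median -1.69, camera adjusted p = 1.56e-13, and adjusted p = 0.108 with an estimated correlation). Eno2 fell from 442 ± 22.5 to 26.2 ± 3.60 CPM and the glucose transporter gene Slc2a1 from 1624 ± 67.2 to 238 ± 27.3 CPM. Ldha fell from 9747 ± 523 to 3998 ± 632 CPM (log2 fold change -1.29 ± 0.10, adjusted p = 3.23e-07). Pdk1 fell from 185 ± 13.2 to 22.2 ± 4.27 CPM (-3.05 ± 0.16, adjusted p = 9.07e-09). Of 43 dioxygenase genes, 25 fell and 5 rose (median -0.56, camera adjusted p = 0.000209, and adjusted p = 0.25 with an estimated correlation). Among the 34 that the HIF list does not hold there were 17 falls and 5 rises. Of 22 TCA cycle genes, 13 rose and 3 fell (median 0.49, camera adjusted p = 0.00803, and adjusted p = 0.292 with an estimated correlation). Cs rose from 157 ± 9.33 to 329 ± 7.52 CPM. Of 61 genes of complexes I to IV, 15 rose and 5 fell (14 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.198). Of 15 ATP synthase genes, 7 rose and 0 fell (6 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.132). Both lists passed without DEF with FeCl3 replicate 3 (adjusted p = 0.00316 and 0.00815). Of 15 mitochondrially encoded genes, 12 fell and 1 rose (median -0.93, camera adjusted p = 0.00482, and adjusted p = 0.417 with an estimated correlation). mt-Co1 fell from 1879 ± 312 to 323 ± 160.4 CPM.

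Of 33 ribosome biogenesis genes, 27 rose and 2 fell (28 rose and 3 fell when adjusted over the list alone; median log2 fold change 1.83, camera adjusted p = 4.34e-10), and the call held with an estimated correlation (adjusted p = 0.00388). Srm rose from 14.4 ± 0.897 to 92.0 ± 7.17 CPM and the rRNA methyltransferase gene Nop2 from 21.03 ± 0.674 to 119 ± 6.63 CPM. Of 50 DNA replication genes, 38 rose and 4 fell (median 0.87, camera adjusted p = 9.31e-08, and adjusted p = 0.292 with an estimated correlation). Of 48 G2/M and mitotic genes, 7 rose and 14 fell (6 rose and 14 fell when adjusted over the list alone; median log2 fold change -0.03, camera adjusted p = 0.26). The spindle checkpoint gene Bub1 fell from 70.3 ± 8.01 to 21.9 ± 3.16 CPM and the kinetochore gene Cenpf from 44.5 ± 2.33 to 17.4 ± 5.13 CPM. The tubulin gene Tubb4b rose from 279 ± 18.6 to 728 ± 106 CPM. Mki67 stood at 91.3 ± 8.77 CPM in DEF and 75.7 ± 16.6 CPM with FeCl3 (log2 fold change -0.27 ± 0.14, adjusted p = 0.111). It was lower when DEF with FeCl3 replicate 3 was left out (-0.46, adjusted p = 0.0014). It passed with limma-voom (0.00756), which gave DEF with FeCl3 replicates 1 and 3 low weights (0.230 and 0.342). Cdkn1a fell from 1079 ± 95.3 to 538 ± 90.2 CPM (adjusted p = 1.01e-05). Of 35 p53 targets, 11 rose and 7 fell (camera adjusted p = 0.333).

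Of 23 ILC2 effector genes, 6 rose and 9 fell (camera adjusted p = 0.567). Areg, which encodes the growth factor amphiregulin, fell from 187 ± 14.5 to 72.4 ± 14.4 CPM and Il10 from 15.1 ± 3.30 to 4.50 ± 0.336 CPM. Of 47 ILC2 identity and receptor genes, 18 rose and 16 fell (19 rose and 17 fell when adjusted over the list alone). Their median of 0.13 and mean of -0.01 differ in sign (camera adjusted p = 0.764). Gata3 rose from 1049.8 ± 72.5 to 1924 ± 117 CPM (log2 fold change 0.87 ± 0.08, adjusted p = 1.41e-06). Il1rl1 rose from 593 ± 102 to 991 ± 193 CPM (0.74 ± 0.14, adjusted p = 0.000716). Tnfrsf9 fell from 3366 ± 128 to 851 ± 56.7 CPM. Of 24 immediate early genes, 12 fell and 3 rose (median -0.50, camera adjusted p = 0.00894, and adjusted p = 0.292 with an estimated correlation). Jun fell from 499 ± 85.9 to 75.6 ± 7.91 CPM. Of 43 ATF4 and amino acid response genes, 28 rose and 10 fell (29 rose and 10 fell when adjusted over the list alone; median 0.61, camera adjusted p = 0.00398, and adjusted p = 0.25 with an estimated correlation). Those that rose include the amino acid transporter Slc7a5 and the proline synthesis gene Aldh18a1 (log2 fold change 1.54 ± 0.08 and 1.68 ± 0.10), and those that fell include Ppp1r15a and Vldlr (-2.30 ± 0.11 and -4.08 ± 0.24). The 3 genes that the ATF4 list shares with the HIF list all fell.

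Of 23 cholesterol synthesis genes, 14 rose and 1 fell (16 rose and 2 fell when adjusted over the list alone; median 0.46, camera adjusted p = 0.00345, and adjusted p = 0.183 with an estimated correlation). Fdps, a farnesyl diphosphate synthase gene, rose from 56.5 ± 4.88 to 176 ± 32.8 CPM. Of 25 type I interferon genes, 13 rose and 2 fell (median 0.86, camera adjusted p = 0.0206, and adjusted p = 0.183 with an estimated correlation), a call lost among genes of at least 10 CPM (adjusted p = 0.207). Ifi35 and Ddx58 rose (log2 fold change 1.38 ± 0.13 and 1.07 ± 0.12) and Isg20 fell (-2.91 ± 0.16). Of 37 fatty acid genes, 18 rose and 7 fell (19 rose and 8 fell when adjusted over the list alone; median 0.26, camera adjusted p = 0.0466, and adjusted p = 0.292 with an estimated correlation). Plin2, a lipid droplet coat gene, rose from 701 ± 60.6 to 1706 ± 131 CPM. The call of the fatty acid list was lost without vehicle replicate 1 (adjusted p = 0.0512), vehicle replicate 3 (0.0562), DEF replicate 1 (0.0677), DEF replicate 2 (0.0519), or DEF with FeCl3 replicate 1 (0.0567) or 2 (0.0515). It was also lost among genes of at least 10 CPM (0.108), with DEF replicates 1 and 2 merged (0.0587) and with the replicate block (0.0508). Of 26 NRF2 target genes, 16 rose and 5 fell (16 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.102, and 0.0347 without DEF with FeCl3 replicate 3). Nqo1 rose from 10.9 ± 0.520 to 143 ± 34.5 CPM. Of 19 glutathione and ferroptosis genes, 8 rose and 4 fell (camera adjusted p = 0.124). The arachidonate lipoxygenase gene Alox5 rose from 69.5 ± 3.57 to 312 ± 34.9 CPM. Of 6 T cell markers, 5 rose and 0 fell (median 0.88, camera adjusted p = 0.0255, and adjusted p = 0.333 with an estimated correlation), a call lost among genes of at least 10 CPM (adjusted p = 0.0656). Trbc2 rose from 27.7 ± 0.752 to 79.9 ± 23.0 CPM, beside Hba-a1, from 3.07 ± 1.44 to 22.1 ± 11.2 CPM. These markers differed between the DEF with FeCl3 libraries. Relative to vehicle, the mean log2 level in replicates 1, 2 and 3 was 0.77, 0.39 and 0.13 for T cell markers and 1.96, -0.30 and 0.71 for red cell markers. It was 1.53, -0.58 and -0.49 for B and plasma cell markers and 1.28, 0.06 and -0.30 for epithelial markers. H2-Ab1 fell from 372 ± 32.8 to 115 ± 27.0 CPM and the chemokine receptor gene Xcr1 rose from 36.6 ± 3.16 to 79.8 ± 7.96 CPM. The 12 macrophage, monocyte and dendritic cell markers had 2 rises and 1 fall (camera adjusted p = 0.764).

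Of 23 NF-kB genes, 6 rose and 10 fell (camera adjusted p = 0.124). Tnfaip3 and Dusp1 fell (log2 fold change -2.54 ± 0.11 and -2.08 ± 0.12). Of 29 heat shock and unfolded protein response genes, 7 rose and 13 fell (7 rose and 14 fell when adjusted over the list alone; camera adjusted p = 0.124). Hspa5 fell (log2 fold change -1.68 ± 0.07) and Hspd1 rose (1.36 ± 0.09). Of 23 autophagy and mitophagy genes, 5 rose and 9 fell (camera adjusted p = 0.132). Bnip3 fell (log2 fold change -4.05 ± 0.15). Of 15 BCL2 family genes, 6 rose and 4 fell (camera adjusted p = 0.658). The pro-apoptotic gene Bcl2l11 fell from 58.5 ± 2.32 to 8.71 ± 0.626 CPM, and Bid rose from 1.55 ± 0.465 to 6.67 ± 0.733 CPM.

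Camera called 14 of 28 lists here, and the calls of HIF targets and ribosome biogenesis, 2 in all, held with an estimated correlation. Adjusted over the list alone, counts were the same in 26 of the 37 lists and differed by at most 3 genes in the other 11. The largest rise was that of Disp2, which had no count in DEF and 32.3 ± 13.4 CPM with FeCl3, at least 426-fold higher. The tubulin gene Tuba8, Maob, the receptor gene Tlr1, the semaphorin gene Sema4a and the RNA polymerase I gene Polr1b rose by 3.34 to 3.95 on the log2 scale (Maob by 4.94 without DEF replicate 2). Large falls included that of Cacna1h, from 19.8 ± 2.13 to 0.123 ± 0.111 CPM. Others were Ascl2, from 50.4 ± 7.33 to 0.431 ± 0.457 CPM, Vwa1, from 234 ± 40.6 to 2.37 ± 0.997 CPM, and Adm, from 466 ± 20.1 to 6.52 ± 1.78 CPM. Without DEF with FeCl3 replicate 1 the log2 fold change of Ascl2 moved from -6.62 to -8.01 and that of Cacna1h from -7.49 to -6.67. Without replicate 2 that of Cacna1h was -8.27.

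Of the 8403 genes that changed in DEF, 5490 changed back with FeCl3, 2692 of them higher and then lower and 2798 lower and then higher. Independent lists of these sizes would share 2194 genes (1056 and 1139). The highest count in 20 simulations with no effect, tested with edgeR, was 0 (at most 189 at an unadjusted p under 0.05). No gene differed between the simulated groups, so a count near 0 was largely built in. It is no measure of the overlap that many unrelated changes would give. Both comparisons use the same 3 DEF libraries, which cannot be divided into parts of at least 2, so part of the excess may come from these shared libraries. The covariance of the fold changes was -1.23, against -0.05 in simulated data with no effect, a difference of -1.18. Pearson's r across genes, which are not independent replicates, was -0.81 against a simulated -0.51. The simulated values show what the shared libraries bring without any change, not what unrelated changes would bring. Genes that changed back and no longer passed against vehicle numbered 3382 (40.2%), 1668 (19.9%) moved back in part, and 440 (5.24%) passed beyond vehicle. A further 1682 (20.02%) had no call of a change with FeCl3 and still passed against vehicle, and 253 (3.01%) moved further. The other 978 (11.6%) passed neither test, which does not show that they stayed at the level of DEF or returned to that of vehicle. The median share of the DEF change that was regained was 65.5% over the 8403 genes (quartiles 32.3% and 97.5%). It was 62.1% to 69.4% in single DEF with FeCl3 libraries. When each DEF library in turn selected the genes and the others measured the share, it was 63.6% to 66.7%. The same vehicle libraries entered both steps, so selection and measurement were not fully separate. The 10 largest changes among these genes were those of Ghrh, Adm, Cacna1h, Cstdc4, Muc2, Gipr, Ascl2, Gad1, Vwa1 and Disp2.

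**Figure D3:**
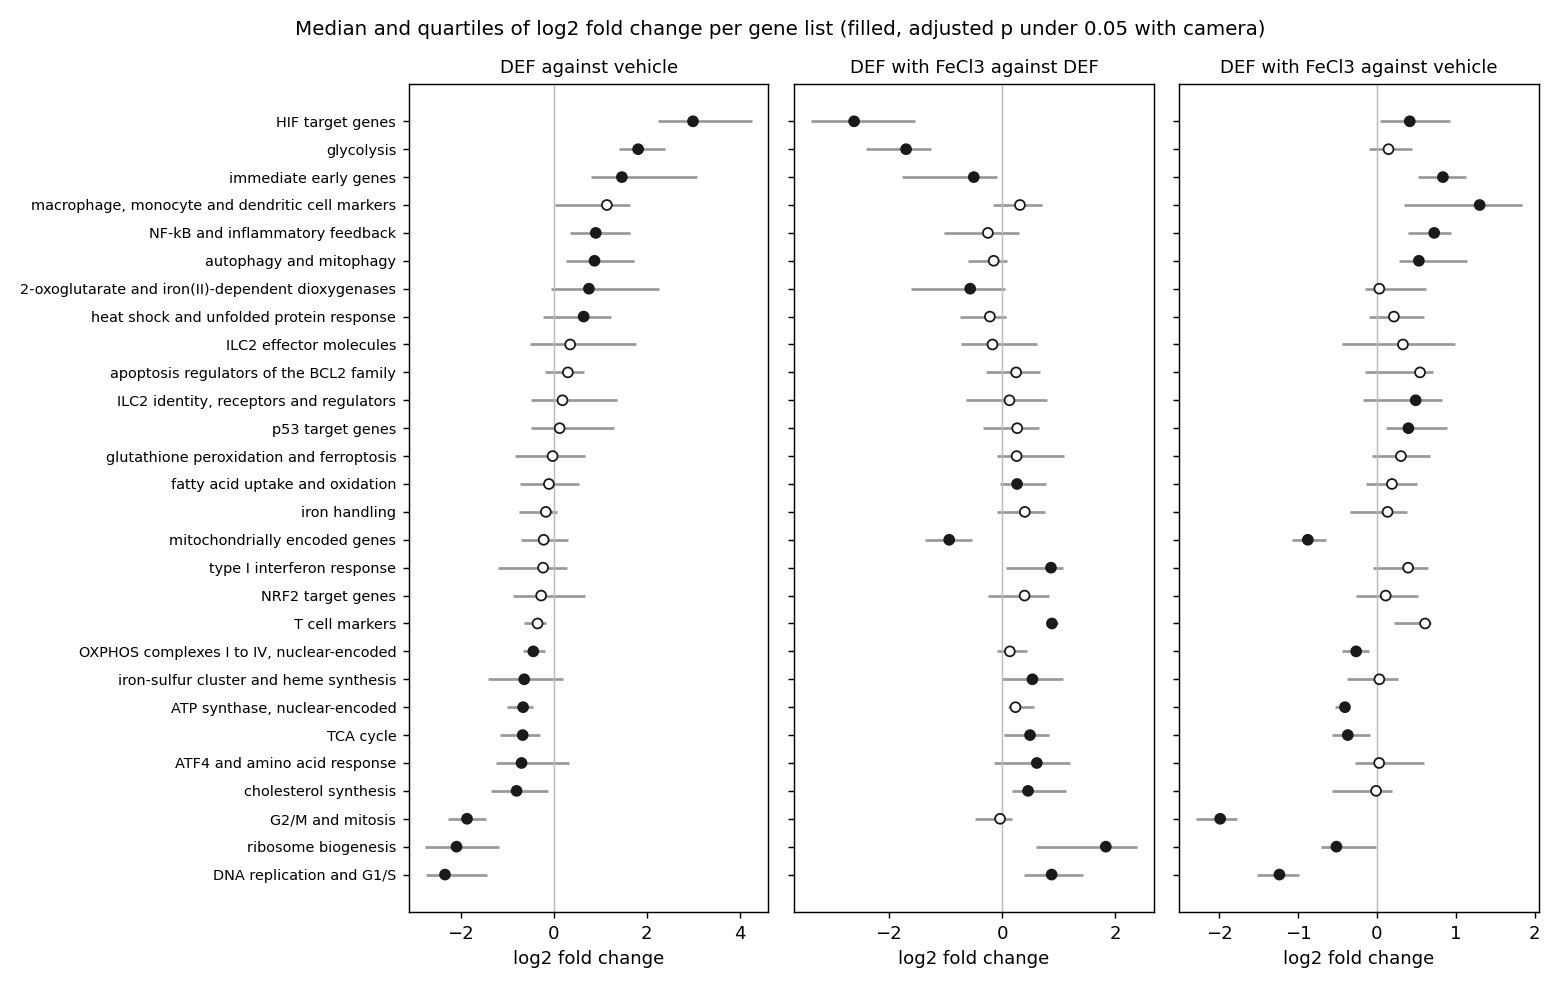
Median log2 fold change (point) and quartiles (line) of the tested genes in 28 gene lists, with a panel for each of the 3 comparisons and filled points for a camera adjusted p under 0.05. HIF targets have medians of 2.99, -2.61 and 0.42 for DEF against vehicle, DEF with FeCl3 against DEF and DEF with FeCl3 against vehicle, and G2/M and mitotic genes -1.86, -0.03 and -1.99.

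The comparison of DEF with FeCl3 against vehicle asks how chelated cells given iron differed from cells kept with vehicle. No group analysed here received FeCl3 without DEF. Il5 was still higher, at 20993 ± 3015 against 7340.0 ± 236 CPM (log2 fold change 1.52 ± 0.09, adjusted p = 9.49e-08), as was Csf2, at 770.3 ± 165 against 214 ± 26.5 CPM. Il13 stood at 180.4 ± 34.7 against 191 ± 23.9 CPM (-0.08 ± 0.14, adjusted p = 0.677). Mki67 was lower, at 75.7 ± 16.6 against 547 ± 13.2 CPM (log2 fold change -2.86 ± 0.14, adjusted p = 2.78e-08). Tfrc, which had no call in DEF against vehicle in the fit of all 3 groups, was lower (-1.21 ± 0.21, adjusted p = 0.000634), at 185 ± 70.0 against 427 ± 16.3 CPM. Of the 14029 genes, 5354 differed (2948 higher and 2406 lower), 1015 at least 2-fold higher and 900 at least 2-fold lower. Of the 5354, 3603 were also called in DEF against vehicle in the same direction and 440 in the opposite direction, and 1311 were not called in DEF. With library totals alone, 44.1% of 5437 were higher, against 55.1% under TMM. The median log2 fold change of all genes moved to -0.10.

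Proliferation genes were below vehicle. Of 48 G2/M and mitotic genes, 46 were lower and 0 higher (median log2 fold change -1.99, camera adjusted p = 3.89e-30), and the call held with an estimated correlation (adjusted p = 0.014). Of 50 replication genes, 49 were lower and 0 higher (median -1.24, camera adjusted p = 5.73e-22, and adjusted p = 0.0631 with an estimated correlation). The ribonucleotide reductase gene Rrm2 stood at 419 ± 86.8 against 1439.7 ± 53.2 CPM, and the kinesin gene Kif11 at 31.6 ± 1.74 against 234 ± 19.8 CPM. Of 33 ribosome biogenesis genes, 20 were lower and 1 higher (median log2 fold change -0.51, camera adjusted p = 0.000457), which held (adjusted p = 0.0429). The nucleolin gene Ncl stood at 283 ± 52.6 against 687 ± 24.7 CPM. Myc was higher (log2 fold change 0.61 ± 0.10). Of 35 p53 targets, 16 were higher and 4 lower (17 higher and 4 lower when adjusted over the list alone; median 0.40, camera adjusted p = 0.0015, and adjusted p = 0.136 with an estimated correlation). Cdkn1a stood at 538 ± 90.2 against 306 ± 13.3 CPM (log2 fold change 0.82 ± 0.12, adjusted p = 0.000116), and the pro-apoptotic gene Bbc3, at 39.1 ± 5.66 against 14.4 ± 1.38 CPM.

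Of 39 HIF targets, 23 were higher and 3 lower (23 higher and 4 lower when adjusted over the list alone; median log2 fold change 0.42, camera adjusted p = 9.03e-06), a call that held with an estimated correlation (adjusted p = 0.0429). Ndrg1 stood at 208 ± 9.54 against 25.3 ± 2.00 CPM, the carbonic anhydrase gene Car9 at 28.7 ± 5.09 against 2.84 ± 0.211 CPM, and P4ha2 at 445 ± 33.3 against 58.8 ± 6.78 CPM. Pdk1 was lower than in vehicle (-0.58 ± 0.15, adjusted p = 0.00878), a call lost without vehicle replicate 3 (adjusted p = 0.0571). Ldha stood at 3998 ± 632 against 4298 ± 154 CPM (-0.10 ± 0.10, adjusted p = 0.441). Of 21 glycolytic genes, 10 were higher and 3 lower (camera adjusted p = 0.117, and 0.0393 without DEF with FeCl3 replicate 3). Of 23 autophagy and mitophagy genes, 15 were higher and 0 lower (median 0.53, camera adjusted p = 2.91e-05, and adjusted p = 0.0631 with an estimated correlation). The autophagy receptor gene Sqstm1 stood at 972 ± 44.9 against 302 ± 11.7 CPM. Of 22 TCA cycle genes, 13 were lower and 1 higher (median -0.37, camera adjusted p = 0.000577, and adjusted p = 0.176 with an estimated correlation). Of 15 ATP synthase genes, 9 were lower and 0 higher (0 higher and 10 lower when adjusted over the list alone; median -0.41, camera adjusted p = 0.0034, and adjusted p = 0.495 with an estimated correlation). Of 61 genes of complexes I to IV, 17 were lower and 1 higher (0 higher and 12 lower when adjusted over the list alone; median -0.26, camera adjusted p = 0.000757, and adjusted p = 0.585 with an estimated correlation). This call was lost without DEF with FeCl3 replicate 3 (adjusted p = 0.126). Of 15 mitochondrially encoded genes, 10 were lower and 0 higher (0 higher and 12 lower when adjusted over the list alone; median -0.88, camera adjusted p = 0.000157, and adjusted p = 0.316 with an estimated correlation). The cytochrome b gene mt-Cytb stood at 232 ± 92.2 against 677 ± 30.8 CPM.

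Of 47 ILC2 identity and receptor genes, 23 were higher and 7 lower (24 higher and 8 lower when adjusted over the list alone; median 0.49, camera adjusted p = 0.00438, and adjusted p = 0.0631 with an estimated correlation). Tnfrsf9 stood at 851 ± 56.7 against 48.6 ± 8.16 CPM, Cd69 at 229 ± 3.32 against 50.3 ± 1.44 CPM, and the inhibitory receptor gene Pdcd1 at 391 ± 26.0 against 168 ± 3.92 CPM. The chemokine receptor gene Ccr2 was lower, at 349 ± 14.4 against 718 ± 21.3 CPM. Gata3 was higher (log2 fold change 0.58 ± 0.08, adjusted p = 9.56e-05). Il1rl1 was higher (0.48 ± 0.14, adjusted p = 0.0166), a call lost without vehicle replicate 1 (adjusted p = 0.0599) or 2 (0.0522), and with library totals alone (0.0582). Of 23 effector genes, 10 were higher and 3 lower (10 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.0778). The list passed without vehicle replicate 1 (adjusted p = 0.0396) or DEF with FeCl3 replicate 3 (0.0177). Of 23 NF-kB genes, 18 were higher and 1 lower (median 0.73, camera adjusted p = 3.15e-06, and adjusted p = 0.106 with an estimated correlation). Of 24 immediate early genes, 15 were higher and 0 lower (16 higher and 0 lower when adjusted over the list alone; median 0.84, camera adjusted p = 1.96e-06, and adjusted p = 0.0804 with an estimated correlation). The adhesion molecule gene Icam1 stood at 171 ± 9.30 against 66.5 ± 7.54 CPM and the transcription factor gene Klf2 at 44.3 ± 2.51 against 9.97 ± 0.887 CPM.

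Ftl1, which like Fth1 had no call in DEF against vehicle, was above vehicle (log2 fold change 0.69 ± 0.15, adjusted p = 0.00288, and 0.45 without DEF with FeCl3 replicate 1). Fth1 was also higher (0.33 ± 0.10, adjusted p = 0.021), a call lost without vehicle replicate 2 (adjusted p = 0.101), vehicle replicate 3 (0.061), or DEF with FeCl3 replicate 1 (0.0518) or 2 (0.0736), and with library totals alone (0.0964) or only these groups fitted (0.0673). Slc40a1 stood at 0.885 ± 0.102 against 0.324 ± 0.237 CPM (1.37 ± 0.64, adjusted p = 0.112). Its adjusted p was 0.0248 with limma-voom, which gave DEF with FeCl3 replicates 1 and 3 low weights. Of 24 iron handling genes, 5 were higher and 4 lower (camera adjusted p = 0.582). In the iron-sulfur and heme list, 5 of 31 were higher and 6 lower, with a median of 0.03 and a mean of -0.10 that differ in sign (camera adjusted p = 0.593). The heme synthesis gene Cpox stood at 55.4 ± 4.23 against 186 ± 0.631 CPM. Of 12 macrophage, monocyte and dendritic cell markers, 6 were higher and 0 lower (median 1.30, camera adjusted p = 0.00665, and adjusted p = 0.229 with an estimated correlation). H2-Ab1 stood at 115 ± 27.0, Cd74 at 20.7 ± 6.23 and Xcr1 at 79.8 ± 7.96 CPM, and Epcam, of the epithelial list, at 26.7 ± 0.593 CPM.

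The remaining lists did not pass against vehicle. Of 43 ATF4 and amino acid response genes, 13 were higher and 9 lower (14 higher and 11 lower when adjusted over the list alone; camera adjusted p = 0.465). Vldlr was higher (log2 fold change 3.12 ± 0.30). Of 43 dioxygenase genes, 13 were higher and 3 lower (camera adjusted p = 0.128). Of 23 cholesterol synthesis genes, 3 were higher and 7 lower (camera adjusted p = 0.135). Of 26 NRF2 targets, 10 were higher and 5 lower (11 higher and 5 lower when adjusted over the list alone; camera adjusted p = 0.289). Of 29 heat shock and unfolded protein response genes, 13 were higher and 4 lower (15 higher and 5 lower when adjusted over the list alone; camera adjusted p = 0.0798). Of 19 glutathione and ferroptosis genes, 7 were higher and 1 lower (8 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.106). Alox5 stood at 312 ± 34.9 against 137 ± 8.15 CPM. For 37 fatty acid genes (11 higher, 3 lower), camera adjusted p was 0.0712, and 0.0393 without DEF with FeCl3 replicate 3. For 6 T cell markers (3 higher, 0 lower; 4 higher and 0 lower when adjusted over the list alone) it was 0.132, and 0.0401 without the same library. For 15 BCL2 family genes (5 higher, 0 lower; 6 higher and 1 lower when adjusted over the list alone) it was 0.0591, 0.0322 without vehicle replicate 1, 0.0278 without DEF with FeCl3 replicate 3 and 0.0268 among genes of at least 10 CPM. For 25 type I interferon genes (7 higher, 2 lower), with the transcription factor gene Irf7 at 10.0 ± 2.97 against 4.19 ± 0.294 CPM, it was 0.0778. The interferon list passed without vehicle replicate 1 (0.0396) or 2 (0.0413), DEF replicate 1 (0.0334), 2 (0.0484) or 3 (0.0405), or DEF with FeCl3 replicate 3 (0.0393), and with DEF replicates 1 and 2 merged (0.0331), each value an adjusted p.

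Camera called 14 of 28 lists against vehicle, and the calls of mitotic genes, HIF targets and ribosome biogenesis, 3 in all, held with an estimated correlation. Adjusted over the list alone, counts were the same in 21 of the 37 lists and differed by at most 6 genes in the other 16. Among the largest differences were those of Ghrh, at 22.2 ± 4.85 CPM with no count in vehicle (at least 332-fold higher), Coch (ratio 186, counting interval 63.5 to 906) and the decoy receptor gene Tnfrsf23, at 119 ± 62.1 against 1.05 ± 0.221 CPM. The acetylcholinesterase gene Ache and the adrenergic receptor gene Adra2a were also higher (log2 fold change 5.53 ± 0.36 and 5.38 ± 0.27). Among the larger falls were those of the antiviral genes Ifitm1 and Ifitm3, Peg10, the fatty acid desaturase gene Fads2 and the mitotic gene Knl1 (log2 fold change -3.92 ± 0.31, -3.16 ± 0.21, -3.31 ± 0.35, -2.89 ± 0.26 and -3.12 ± 0.14). Ifitm1 stood at -4.56 without DEF with FeCl3 replicate 1, and Ache at 6.29 without vehicle replicate 3. The fitted log2 fold change of Coch was 7.38, and 6.76 without vehicle replicate 1 or 8.37 without vehicle replicate 2.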

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

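The setting with library totals only was chosen after the data were seen; the others were set before the data were examined. A minimum log2 fold change of 1, which leaves fewer genes by construction, gave 4778 genes for DEF against vehicle, 3531 for DEF with FeCl3 against DEF, 1915 for DEF with FeCl3 against vehicle and 2557 changed back. With an estimated correlation, camera called 3, 2 and 3 lists in these comparisons in place of 16, 14 and 14. Genes of a list that vary together carry less information, but whether this accounts for the loss was not tested. The test fry, which does not compare a list with other genes, called 24, 22 and 26. Leaving out 1 library in turn gave 7524 to 9231, 6341 to 8057 and 4197 to 6130 genes, 4793 to 5968 changed back, and a median share regained of 64.1% to 68.6%. It gave 15 to 16, 13 to 17 and 14 to 19 lists. With 2 libraries left in a group, its spread is estimated together with the other groups. The other settings stayed within 1.5 times of these counts. Fitting only the groups compared, which does not share spread with the third group, gave 9453, 6523 and 4816 genes, against 8403, 7329 and 5354. DESeq2 gave 8507, 7467 and 5651 genes, and voom 9803, 8315 and 7096. The quality weights of voom were 0.230, 1.98 and 0.342 for DEF with FeCl3 replicates 1, 2 and 3. Its values for that group thus rest largely on replicate 2. A minimum of 10 CPM gave 6587, 5923 and 4694 of the fewer genes it tests, with 13, 10 and 15 lists. That minimum ended the calls of the iron-sulfur and heme (0.104), ATF4 (0.0538) and heat shock (0.0537) lists for DEF against vehicle. For DEF with FeCl3 against DEF it ended those of the iron-sulfur and heme (0.0954), fatty acid (0.108), interferon (0.207) and T cell (0.0656) lists. Library sizes without mitochondrially encoded genes moved no count. TMM factors are computed anew from the same counts and take up such a change, so this was largely fixed in advance. The same holds for the 435 comparisons of named genes under this setting, all of which kept direction and side of the threshold. The share regained was 65.4% both with RLE factors and over all genes with a log2 fold change of at least 1. Replicate numbers did not pair the libraries, since same-number correlations of deviations from the group means were -0.0548 to 0.0731, 0 pairs were over 0.1, and 1 library of 9 correlated best with its own number. With the replicate block, 8351, 7297 and 5335 genes were called, 5465 changed back, and 16, 13 and 14 lists passed. The fatty acid list in DEF with FeCl3 against DEF did not pass (adjusted p = 0.0508). Merging DEF replicates 1 and 2 gave 7667, 6433 and 5158 genes, and 16, 13 and 15 lists. Over 435 values of genes named in the text, 8503 of 8680 comparisons with an alternative kept direction and side of the threshold, 104 lost the call, 73 gained one and 0 reversed. For lists these were 1157 of 1260, 56, 47 and 0. For calls lost or gained other than by a smaller number of libraries or genes, the cause was not tested. Depth limits genes with few counts. Slc40a1, with 8 counts over the DEF libraries, lost its call for DEF with FeCl3 against DEF without any 1 of 4 libraries (adjusted p = 0.136 without DEF replicate 2), with no filter (0.0523) and with DEF replicates 1 and 2 merged (0.0651), and whether depth is the cause was not tested.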

Other observations

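The tests of explanations and of other splits of the libraries in this part were chosen after the results they bear on had been seen, while the tests of genes and lists were set before the data were examined. Of 46 tested histone genes, a group taken by symbol after the data were seen, 16 rose in DEF, 21 fell and 9 did not pass. With FeCl3 against DEF, 13 rose, 7 fell and 26 did not pass. The 46 include the pseudogenes H3f3a-ps1 and H3f3a-ps2, which passed in no comparison. Many of the 46 are near-identical copies, so the split of reads between them is uncertain. Hist1h2ap, an H2A gene, stood at 692 ± 20.9, 18.9 ± 2.40 and 194 ± 82.4 CPM in vehicle, DEF and DEF with FeCl3, and the linker histone gene H1f4 at 54.5 ± 20.6, 2.68 ± 0.604 and 16.0 ± 6.59 CPM. They were lower in DEF and in part higher again with FeCl3 (log2 fold changes of H1f4 -4.40 ± 0.37, 2.65 ± 0.36 and -1.75 ± 0.30 for DEF against vehicle, DEF with FeCl3 against DEF, and DEF with FeCl3 against vehicle). H2bc4 stood at 7.10 ± 0.851, 147 ± 10.0 and 120.5 ± 5.72 CPM, H2ac18 at 4.27 ± 0.569, 74.3 ± 4.95 and 101.3 ± 20.3 CPM, and the linker histone gene H1f2 at 17.8 ± 2.82, 110.4 ± 11.0 and 172 ± 17.3 CPM. These were higher in DEF and still higher than vehicle with FeCl3 (log2 fold changes of H1f2 2.63 ± 0.14, 0.64 ± 0.13 and 3.27 ± 0.14). Of 6 replicative helicase genes, Mcm2 to Mcm7, the median share regained was 56.6%, against 42.3% over the 50 replication genes and -1.33% over the 48 mitotic genes.

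Ero1l, which encodes an oxidoreductase of the endoplasmic reticulum that helps form disulfide bonds, was among the most abundant transcripts in DEF, at 29928 ± 1768 CPM against 3760.2 ± 316 in vehicle and 6164 ± 345 with FeCl3, or 2.68%, 0.413% and 0.628% of all counts. Furin, a proprotein convertase gene, moved further with FeCl3, from 4649 ± 379 CPM in vehicle to 7507 ± 787 in DEF and 14551 ± 901 with FeCl3 (log2 fold changes 0.69 ± 0.09, 0.95 ± 0.09 and 1.65 ± 0.09, the first 0.40 with library totals alone). Mitochondrial transcripts moved apart in DEF, where mt-Co1 and both mitochondrial rRNAs rose while mt-Nd1 stood at 314 ± 62.7 against 542 ± 32.5 CPM and mt-Cytb at 402 ± 62.8 against 677 ± 30.8 CPM.

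H2-Ab1 gained 355 CPM in DEF while its partner genes gained little. Antigen-presenting cells in the DEF libraries would bring Cd74 at least as abundantly, but Cd74 gained 12.7 CPM, 3.57% of the gain of H2-Ab1 (at most 4.02% in a single DEF library). The Cd74 value argues against such cells as the source. H2-Aa and H2-Eb1 gained 0.412% and 0.411%, which cannot weigh on this, since their counts may be lowered by differences from the reference genome. A response of the ILC2s themselves stays open, as do differences between the class II genes of BALB/c mice and the reference genome, which were not tested and which may lower the counts of single class II genes in every group.

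The DEF with FeCl3 libraries lay further apart than those of the other groups, with a median SD of 0.21 log2 units over 8682 genes against 0.09 in vehicle and 0.12 in DEF. In replicates 1, 2 and 3, Tfrc stood at 107, 203 and 243 CPM, Ftl1 at 10075, 7159 and 5830.0 CPM, and Hist1h2ap at 282, 181 and 118 CPM. Markers of other cells differed as well, with mean log2 levels relative to vehicle of 1.96, -0.30 and 0.71 for red cells and 1.53, -0.58 and -0.49 for B and plasma cells. A low or unequal depth is argued against as the whole cause. Replicates 2 and 3, with 13704865 and 12668327 counts, differed by a median of 0.21 log2 units. Pairs of the other groups, with totals of 10102180 to 25295252 counts, differed by at most 0.17. RNA of other cells stays open, although the cells had been sorted and these means rest on 2 of 8 listed red cell markers and 2 of 10 listed B and plasma cell markers. A candidate explanation is that the cultures differed in how far they responded to FeCl3, but the correlation across genes between the difference of replicates 1 and 3 and the response of replicate 2 was only 0.16. That leaves it open, and genes are not independent replicates.

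With FeCl3 against DEF, 38 of 50 replication genes rose and 4 fell, while 7 of 48 mitotic genes rose and 14 fell, a difference of list medians of 0.91 on the log2 scale. The call of the replication list was lost with an estimated correlation (adjusted p = 0.292). Gene abundance alone did not give such a difference of medians, since 0% of 10000 pairs of random lists matched on mean expression differed by as much (the central 95% of them reached 0.37). Random genes need not vary together as the genes of a list can, so the 0% is no measure of chance. The mean log2 level of replication minus mitotic genes was -0.80 to -0.82 in the DEF libraries, 0.16 to 0.33 in those with FeCl3 and -0.45 to -0.48 in vehicle. The 2-sided exact permutation p was 0.1 for FeCl3 against DEF, the smallest that 3 against 3 libraries allow. A candidate explanation is that cells had returned to DNA synthesis and not yet to mitosis after 8 h with iron. It is a hypothesis, and DNA content or nucleotide incorporation, which would test it, was not analysed here.

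For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Every split but the real one mixes libraries of both groups, so a low count of genes there was largely built in and is no measure of chance. With edgeR, DEF against vehicle gave 8403 genes and the highest of the other splits 0 (106 at an unadjusted p under 0.05), DEF with FeCl3 against DEF gave 7329 against 0 (827), and DEF with FeCl3 against vehicle gave 5354 against 0 (807). In each, 1 of 10 splits, the real one, was as large. For gene lists called by camera, the real splits gave 16, 14 and 14 and the highest other splits 15, 12 and 15, so that 1, 1 and 2 of 10 were as large. Mixed groups could thus give nearly as many lists, so the number called at the preset correlation does not set the real groups apart. Of 100 assignments of the 9 libraries to 3 groups, 1, the real one with 5490 genes changed back, reached that count. Most other assignments mixed DEF libraries with those of other groups, which lowers the count by construction, so they are no measure of chance. The highest other count was 4302, in an assignment that kept the 3 DEF libraries together and mixed those of vehicle and DEF with FeCl3. The count thus largely reflects how DEF differs from the other libraries.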
